A study of Mus musculus with 15 samples.

How the data were processed

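The labels describe female Swiss Webster mice given the colon carcinogen azoxymethane at 7.4 mg/kg, followed by 3 cycles of 4% dextran sulfate sodium, a compound that injures the colon lining. Each cycle held 7 days of dextran sulfate sodium and 21 days of water. The mice were 7 weeks old at the start and 9 weeks old at the first cycle, and were killed at 18 weeks. They received either 5-aminosalicylic acid (5-ASA, mesalamine, an anti-inflammatory drug) at 75 mg/kg or vehicle. Inflamed or polypoid colon areas were cut by laser capture from frozen sections. The captured RNA went through 2 amplification rounds, was labelled, and was hybridised to long-oligonucleotide mouse arrays beside a universal mouse reference RNA in the other dye.

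Per the file headers, the scanner files hold intensity values for each spot and channel, mean spot brightness and median local background, read by Agilent Feature Extraction 9.1.1.1. The same deposited files also hold background-subtracted, dye-normalised signals in intensity units, which served as an alternative. The deposited value table holds log2 of sample over reference, with the dye-swapped arrays already turned. Its background correction and normalization were not given in the sources used here. Its slope against the scanner's log10 ratio was 3.19 to 3.25 in size over bright spots, and its column medians lay between -0.012 and 0.031. Across probes it correlated with the values computed here at r of 0.997 or above on each array, and it also served as an alternative.

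Each array had 43790 spots, of which 2256 were controls. The 41174 probes were named through a mouse reference table (GRCm38.p6, used for gene names only). By RefSeq accession, 22864 probes received a name, 10230 more did so by gene name or unique synonym, and 8080 kept the name on the array. Accession and name gave different symbols for 66 probes, for which the accession was used. No genome position is given because the array files name no genome build.

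Values were computed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected by normexp with an offset of 50, the channels were brought together by loess within each array, and the swapped arrays were turned so that a value is log2 of sample over reference. Spots called non-uniform or population outliers by the scanner software were left out. A fit of animal plus dye over the 15 arrays gave 1 value per gene for each of the 8 animals, which removed the dye effect of each probe. Probes were kept when the sample channel was well above background on every array of at least 1 group, and each gene was represented by its probe with the highest mean brightness. This left 21300 genes, of which 2 lacked a value in 1 sample.

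The 4 groups of 2 animals were compared in limma with group means and a shared estimate of the spread (4 residual degrees of freedom, prior degrees of freedom 2.14). The 7 comparisons were polypoid over inflamed tissue in both arms together and in each arm, 5-ASA over untreated in both tissues together and in each tissue, and the difference of the treatment effect between tissues. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. If no gene changed, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. On simulated data, with 200 changed genes of 21300 in each of 5 draws, 46.0% of 2-fold and 86.8% of 4-fold changes were recovered for polypoid over inflamed tissue. For 5-ASA the recovery at 2-fold and 4-fold was 48.4% and 88.4% in both tissues together, 12.4% and 70.0% in polypoid tissue and 18.4% and 64.8% in inflamed tissue, with 3.9% to 5.9% false calls over the tested comparisons. The simulated values were drawn independently for each gene, with no shift between scan sessions and no correlation between genes. Recovery in the real data may therefore be lower, and the simulation does not rule out changes of these sizes. The number of animals, 2 per group, limits the precision.

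The 30 gene lists (pathways and markers of cell types that a captured area could hold) were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Of their 756 entries, 752 matched a current symbol. Lists were tested by camera in limma with a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, in 1 direction and does not compare a list with other genes.

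Named genes were chosen by a rule. For each of 4 comparisons it took the 10 rising and 10 falling genes with the largest changes among those that passed the threshold and had the same direction in every sample, filled up by the smallest unadjusted p where fewer passed. To these it added up to 4 members with the smallest p of each list that passed camera. The rule gave 272 entries with 200 distinct genes, of which 68 entries passed. Values of other named genes are given where a count of a list is small, and these genes were chosen after their values were seen.

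The scan dates in the headers fell into 4 sessions. Session 1 held untreated inflamed replicate 1 and treated inflamed replicate 1, and session 2 held untreated polypoid replicate 1 and treated polypoid replicate 1. Session 3 held the second replicates of both polypoid groups and of untreated inflamed tissue, and session 4 held treated inflamed replicate 2 alone. Values within a session are differences between the samples of that session. Session was also fitted as a fixed block, which left 1 residual degree of freedom. Only session 3 held both tissues, so with this block the tissue difference runs through untreated inflamed replicate 2. The alternatives covered the background correction, the normalization, the filter, the dye term, the use of arrays, the probes of a gene, the variance model, sample weights, blocks and the leaving out of each sample. Per-gene expression was the only measurement, and no sample was left out of the values reported first.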

Results

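The data were 15 dual-colour arrays from 8 mice, 2 in each of 4 groups: inflamed and polypoid colon tissue of untreated mice, and inflamed and polypoid colon tissue of mice given 5-ASA. Each mouse gave tissue to 1 group. For 7 mice the dyes were swapped on a further array, and treated inflamed replicate 2 had 1 array, with the sample in Cy3. The median sample intensity was 148.6 to 257.2 scanner units per array over a median local background of 41 to 63. The share of spots well above background in the sample channel was 57.4% to 90.9%, and the lowest share belonged to treated inflamed replicate 2. Across genes, which are not independent replicates, the 2 samples of a group correlated at r = 0.872 in untreated inflamed, 0.943 in treated inflamed, 0.873 in untreated polypoid and 0.916 in treated polypoid tissue. The first principal component held 48.5% of the variance and placed the inflamed samples between -50.3 and -28.5 and the polypoid samples between 14.2 and 57.9. Untreated polypoid replicate 1 lay at 14.2. Across genes it correlated at 0.902 with treated polypoid replicate 1, 0.891 with treated inflamed replicate 2 and 0.873 with the other sample of its own group. Untreated inflamed replicate 1 correlated at 0.948 and 0.92 with treated inflamed replicates 1 and 2 and at 0.872 with its group mate. The second component held 18.6% of the variance. It placed the samples of scan sessions 1 and 2 between 16 and 25.1 and those of sessions 3 and 4 between -52 and 2.4. P-values measure differences against the spread between animals of a group. The 2 animals of each group were scanned in different sessions, so this spread also holds any difference between sessions.

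The comparison of polypoid with inflamed tissue over both treatment arms (4 samples of each tissue) asked how gene expression in the polyps of this model differed from that in inflamed mucosa. The Wnt inhibitors Nkd1 and Notum, the calprotectin genes S100a8 and S100a9 and the chemokine Cxcl5 rose in polypoid tissue, and the colonocyte exchanger Slc26a3 and the endocrine hormone Insl5 fell. Cxcl5, a chemokine that attracts neutrophils, rose 53.8-fold (log2 5.75 ± 0.42 SE, limma adjusted p = 0.0043), and the secreted Wnt inhibitor Wif1 rose 40.6-fold (5.34 ± 0.36, adjusted p = 0.0038). Hao2, a peroxisomal hydroxyacid oxidase, fell 36.8-fold (-5.20 ± 0.87, adjusted p = 0.028), and Pck1, a key enzyme of gluconeogenesis, fell 24.3-fold (-4.60 ± 0.78, adjusted p = 0.029). Within scan session 3 Cxcl5 differed by 5.42, Wif1 by 5.61 and Hao2 by -6.12. The polypoid samples varied among themselves for the genes that fell. Treated minus untreated polypoid tissue was -6.83 within session 2 and -3 within session 3 for Hao2, and -5.03 and -0.77 for Pck1. It was 1.15 and -0.65 for Cxcl5 and 0.42 and 0.52 for Wif1. Of 21300 genes, 1265 passed, 846 higher and 419 lower in polypoid tissue, and 4647 genes (21.8%, against 5.6% by chance) had no overlap between the tissues in either arm and the same direction in both arms.

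**Figure D1:**
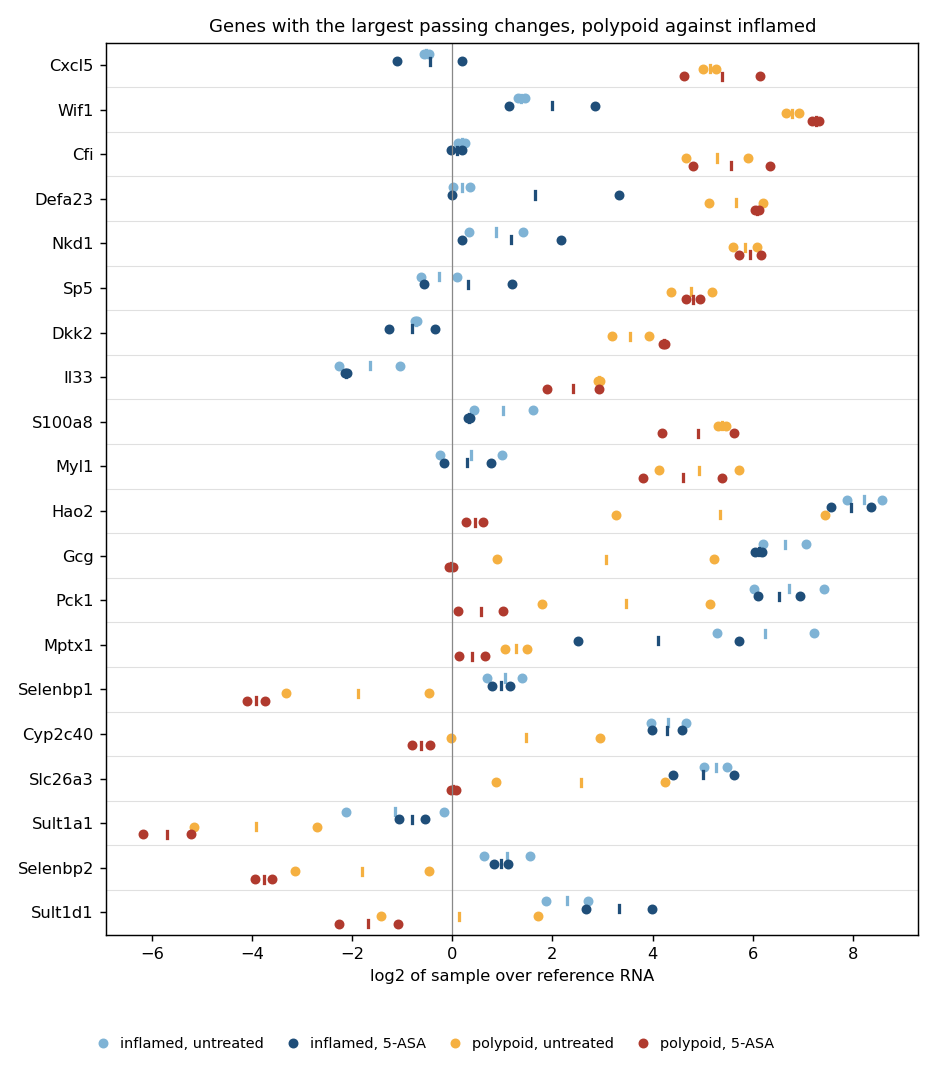
Log2 of sample over reference RNA on the horizontal axis for the 10 genes that rose most and the 10 that fell most in polypoid against inflamed tissue by the rule for named genes. Points are samples, vertical bars are means of the 2 samples of a group, and colours are the 4 groups; Cxcl5 lay between -1.10 and 0.19 in the inflamed samples and between 4.62 and 6.15 in the polypoid samples.

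Of the 24 measured Wnt and beta-catenin target genes, 20 rose and 1 fell, and the counts were 20 and 1 adjusted over the list alone. The list's median log2 difference was 2.26, with 2.80 within scan session 3 and 2.73 with session as a block (camera adjusted p = 3.8e-19; adjusted p = 0.13 with an estimated correlation; fry adjusted p = 0.0021). Nkd1 (29.3-fold) and the deacylase Notum (12.8-fold), both feedback inhibitors of Wnt signalling, rose, as did the transcription factor Sp5 (27.3-fold), the feedback regulator Axin2 (11.1-fold) and the matrix protease Mmp7 (15.5-fold). The member that fell was Ascl2, a stem cell transcription factor (-0.53 ± 0.10, adjusted p = 0.042), which was named after its value was seen. Outside the list, Dkk2, a secreted modulator of Wnt receptors, rose 25.3-fold. In inflamed tissue Notum was well above background on 3 of 7 arrays, Dkk2 on 4 of 7 and Sp5 on 6 of 7.

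Among 25 genes of stem cells and fetal-like repair epithelium, 8 rose and 2 fell, or 13 and 2 adjusted over the list alone, with a median of 0.82, 1.04 within scan session 3 and 1.07 with session as a block (camera adjusted p = 1.6e-06; adjusted p = 0.13 with an estimated correlation; fry adjusted p = 0.0040). The stem cell receptor Lgr5 rose 15.7-fold (3.97 ± 0.47), the alarmin Il33 rose 23.7-fold, the keratin Krt7, saturated on 4 of 8 polypoid arrays, rose (1.72 ± 0.22) and the tight junction gene Cldn4 rose 2.66-fold, with Cldn4 well above background on 6 of 7 inflamed arrays. The members that fell were Ascl2, which like Lgr5 is also in the Wnt list, and Msi1 (-1.37 ± 0.25, adjusted p = 0.034), both named after their values were seen. Defa23, an antimicrobial defensin of Paneth cells, rose 31.0-fold (4.96 ± 0.72), with 4 of 7 inflamed arrays well above background. Cfi, a complement regulator, rose 39.4-fold and the myosin light chain Myl1 rose 21.5-fold.

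Of 30 mature colonocyte genes, 10 fell and 1 rose, or 15 and 1 adjusted over the list alone, with a median of -1.02, -0.99 within scan session 3 and -1.05 with session as a block (camera adjusted p = 2.1e-09; adjusted p = 0.38 with an estimated correlation). Slc26a3, the chloride-bicarbonate exchanger of the colon surface, fell 14.4-fold (-3.85 ± 0.74), the water channel Aqp8 fell 10.1-fold (-3.34 ± 0.42), and the sulfate transporter Slc26a2 fell 4.57-fold. Treated minus untreated polypoid tissue was -4.18 within scan session 2, which held untreated polypoid replicate 1, and -0.91 within session 3 for Slc26a3. It was -4.79 and -2.78 for Aqp8 and -0.92 and -0.78 for Slc26a2. Selenbp1 fell 15.2-fold, its close relative Selenbp2 fell 14.1-fold, and the adhesion gene Ceacam20 fell 2.12-fold. Selenbp1 was saturated on 5 and Selenbp2 on 4 of 7 inflamed arrays, which understates their folds. The sodium-proton exchanger Slc9a3, named after its value was seen, was the member that rose (1.56 ± 0.29, adjusted p = 0.036). The sulfotransferases Sult1a1 and Sult1d1 fell 14.3-fold and 12.0-fold, the latter at an adjusted p of 0.049, and the cytochrome Cyp2c40 fell 14.8-fold. Mptx1, a pentraxin of intestinal epithelium, fell 20.5-fold and was well above background on 7 of 8 polypoid arrays and saturated on 3 of 7 inflamed arrays.

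Of 20 enteroendocrine cell genes, 4 fell and 1 rose, or 8 and 1 adjusted over the list alone (median -0.56; -0.47 within scan session 3; -0.30 with session as a block; camera adjusted p = 4.8e-05; adjusted p = 0.38 with an estimated correlation). Gcg, which encodes proglucagon, fell 29.1-fold by 1 of its 2 probes, while the other probe had the opposite sign. Insl5, a hormone of colonic endocrine cells, fell 11.5-fold, the granule proteins Chga and Chgb fell 6.63-fold and 10.7-fold, and the transcription factor Isl1 rose (0.67 ± 0.11), with Chgb named after its value was seen. The polypoid samples varied: within scan sessions 2 and 3 treated minus untreated polypoid tissue was -5.3 and -0.88 for Gcg and -3.66 and -0.53 for Insl5. It was -2.25 and -0.11 for Chga and -4.91 and -1.23 for Chgb. Of 22 goblet cell genes, the mucus protein gene Fcgbp fell 1.99-fold and was the only call, against 3 adjusted over the list alone, with a median of -0.75, -0.52 within scan session 3 and -0.54 with session as a block (camera adjusted p = 0.00014; adjusted p = 0.38 with an estimated correlation). Klk1 (-2.42 ± 0.57), Capn9 (-1.25 ± 0.30) and Retnlb (-0.95 ± 0.27) had adjusted p-values of 0.065, 0.066 and 0.098, with Retnlb saturated on 5 of 7 inflamed arrays. Without untreated polypoid replicate 2 the goblet median was -0.43.

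Of 18 neutrophil genes, 7 rose, or 12 adjusted over the list alone, and all 18 had positive differences (median 1.03; 0.68 within scan session 3; 0.59 with session as a block; camera adjusted p = 5.3e-09; adjusted p = 0.38 with an estimated correlation; fry adjusted p = 0.036). The calprotectin subunits S100a8 and S100a9 rose 22.2-fold and 20.0-fold (4.47 ± 0.39 and 4.32 ± 0.19), the iron-binding lipocalin Lcn2 rose 15.2-fold and Retnlg rose 6.23-fold. S100a8 was well above background on 6 of 7 inflamed arrays, Lcn2 on 3 of 7 and Retnlg on 2 of 7. Of 26 inflammatory cytokines and chemokines, 5 rose, or 6 adjusted over the list alone, with a median of 0.64, 0.26 within scan session 3, 0.14 with session as a block and 0.24 without treated polypoid replicate 1 (camera adjusted p = 0.00045; adjusted p = 0.50 with an estimated correlation). They were Cxcl5, Il33, the neutrophil chemokine Cxcl1 (14.0-fold), the monocyte chemokine Ccl7 (2.75-fold, well above background on 5 of 7 inflamed arrays) and Il1b (9.33-fold), the last named after its value was seen.

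Of 35 cell cycle genes, 7 rose, or 10 adjusted over the list alone, and 34 had positive differences (median 0.53; 0.10 within scan session 3; 0.49 with session as a block; camera adjusted p = 4.9e-08; adjusted p = 0.43 with an estimated correlation). The replication helicase subunits Mcm4 and Mcm6 rose 2.30-fold and 1.67-fold, the ribonucleotide reductase subunit Rrm1 rose 1.88-fold and the licensing factor Cdt1 rose 1.52-fold. Of 25 DNA damage and replication checkpoint genes, Brca2 (1.92-fold, though not in every sample) and Cdc25a (1.70-fold) rose and Trp53 fell 4.26-fold by 1 of its 2 probes, while Msh6 (0.69 ± 0.15) had an adjusted p of 0.056. The list's median was 0.25, with 0.42 within scan session 3, 0.68 with session as a block and 0.47 without untreated inflamed replicate 1, and adjusted over the list alone 6 genes rose and 2 fell (camera adjusted p = 0.0095; adjusted p = 0.38 with an estimated correlation).

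Of 40 oxidative phosphorylation genes, 4 fell, or 15 with 1 that rose adjusted over the list alone, and 36 had negative differences (median -0.41; -0.43 within scan session 3; -0.41 with session as a block; camera adjusted p = 1.6e-07; adjusted p = 0.13 with an estimated correlation; fry adjusted p = 0.0057). The complex I subunits Ndufb9, Ndufa9 and Ndufb8 fell 1.83-fold, 1.73-fold and 1.66-fold, and the complex IV subunit Cox7a2 fell 1.63-fold. Of 24 PPAR target genes, 3 fell and 2 rose, or 9 and 3 adjusted over the list alone, with a median of -0.42, -0.10 within scan session 3, -0.30 with session as a block and -0.66 without treated inflamed replicate 2 (camera adjusted p = 0.013; adjusted p = 0.55 with an estimated correlation). The fatty acid oxidation enzyme Cpt1a fell 1.71-fold, and the lipid droplet gene Plin2, named after its value was seen, fell 1.43-fold. The pyruvate dehydrogenase kinase Pdk4 rose 6.28-fold and malic enzyme Me1 rose 3.63-fold.

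Of 17 smooth muscle genes, 4 fell, or 6 adjusted over the list alone, with a median of -1.20 and -0.91 within scan session 3 (camera adjusted p = 0.00037; adjusted p = 0.39 with an estimated correlation). With session as a block the median of this list was 0.12, the opposite sign, and without untreated inflamed replicate 1 it was -0.58. The contractile genes Lmod1, Cnn1, Tagln and Myl9 fell 4.27-fold, 4.01-fold, 3.29-fold and 2.93-fold. Of 19 B and plasma cell genes, the chaperone Mzb1 fell 3.31-fold, though not in every sample, and Sdc1, a proteoglycan also made by epithelium, rose 2.30-fold. The list's median was -0.63, with -0.38 within scan session 3 and -0.16 with session as a block, and adjusted over the list alone 4 genes fell and 1 rose (camera adjusted p = 0.0018; adjusted p = 0.38 with an estimated correlation). It was -0.28 without untreated inflamed replicate 1 and -1.08 without untreated inflamed replicate 2. Pou2af1 (-1.76 ± 0.44) and Jchain (-1.76 ± 0.47) had adjusted p-values of 0.078 and 0.086.

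Of 21 T and NK cell genes, 1 rose, Tcf7 (4.10-fold, by 1 of its 2 probes), which is also a Wnt target in the fixed lists, and the count was 1 adjusted over the list alone. This list's median was -0.25, with -0.06 within scan session 3 and -0.03 with session as a block (camera adjusted p = 0.0050; adjusted p = 0.39 with an estimated correlation). Cd3d (-0.86 ± 0.21) and Nkg7 (-1.30 ± 0.34) had adjusted p-values of 0.076 and 0.083. Of 15 enteric neuron and glia genes, Stmn2 fell 2.23-fold by 1 of its 2 probes, the only call also when adjusted over the list alone (median -0.22; -0.13 within scan session 3; -0.05 with session as a block; camera adjusted p = 0.0039; adjusted p = 0.30 with an estimated correlation; fry adjusted p = 0.036). In limma none of 30 interferon response genes passed, nor did any adjusted over the list alone, and 26 had negative differences. The interferon list's median was -0.49, with -0.04 within scan session 3 and -0.38 with session as a block (camera adjusted p = 0.00076; adjusted p = 0.55 with an estimated correlation), and its members with the smallest p were Psmb9 (-1.09 ± 0.27), Cd74 (-1.11 ± 0.31), Rsad2 (-1.56 ± 0.45) and Usp18 (1.0 ± 0.29), with adjusted p-values of 0.072 to 0.11. Without untreated inflamed replicate 1 the interferon median was -0.30, and without treated inflamed replicate 1 it was -0.24. By arm, the interferon median was 0.02 in untreated mice and -0.99 in mice given 5-ASA.

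**Figure D2:**
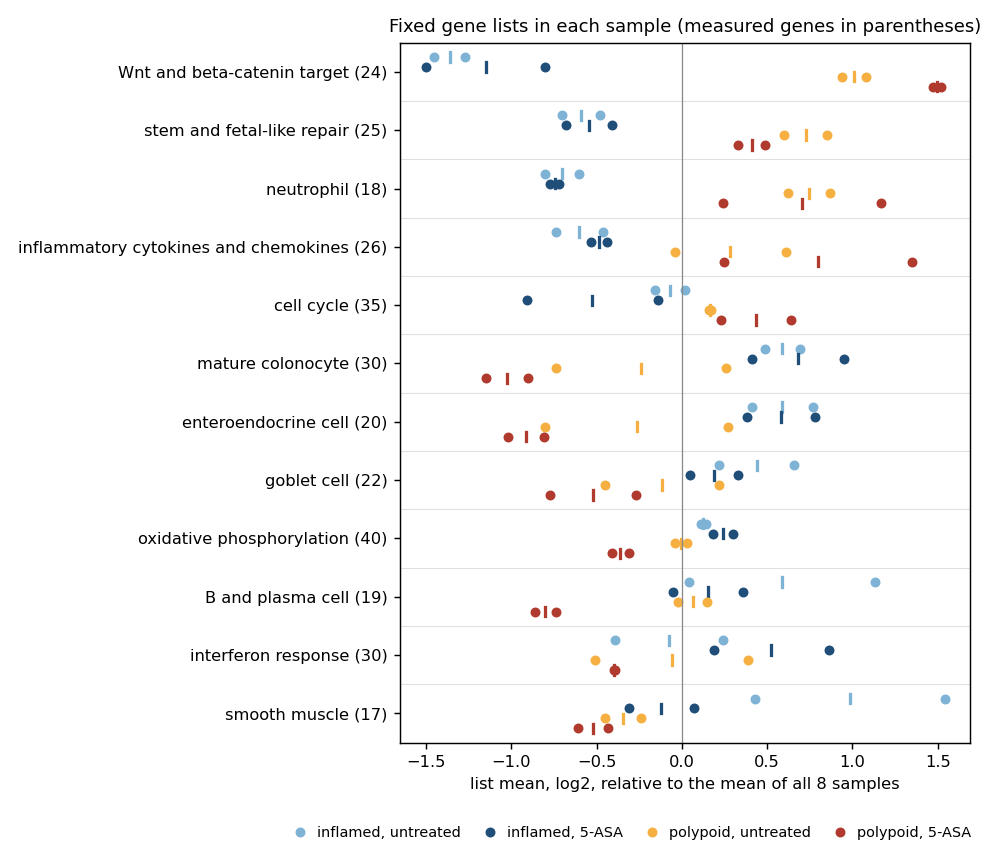
Mean of each of 12 fixed gene lists (log2, relative to the mean of all 8 samples) on the horizontal axis. Points are samples, vertical bars are means of the 2 samples of a group, and colours are the 4 groups; the Wnt list was at most -0.80 in inflamed and between 0.94 and 1.52 in polypoid samples, and the smooth muscle list was highest in untreated inflamed replicate 1, at 1.54.

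Within scan session 3, all 1265 genes called for polypoid over inflamed tissue kept their sign, but they were called from data that held those 3 samples. The fit with session as a block used the same genes and samples. Only session 3 held both tissues, so that fit is not a check apart from session 3. With session as a block, limma called 0 genes (3054 at an unadjusted p under 0.05, smallest adjusted p 0.33, 1 residual degree of freedom), while all 1265 kept their sign with a median size of 1.20 against 1.1. The count was 125 without treated inflamed replicate 1, 361 without treated polypoid replicate 2, 364 without treated polypoid replicate 1, 462 without treated inflamed replicate 2, 687 without untreated polypoid replicate 2 and 765 without untreated inflamed replicate 2.

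In untreated mice, Cxcl5 rose 50.5-fold (log2 5.66 ± 0.59 SE, limma adjusted p = 0.040), Wif1 42.6-fold, Il33 24.0-fold, Mmp7 20.6-fold and S100a9 16.8-fold in polypoid over inflamed tissue (2 samples against 2). The clock output gene Dbp was the only call that fell (-1.44 ± 0.14, adjusted p = 0.039). In mice given 5-ASA, Cxcl5 rose 57.3-fold (5.84 ± 0.59, adjusted p = 0.016), Wif1 38.7-fold and S100a9 23.7-fold, while Hao2 fell 184-fold (-7.52 ± 1.24, adjusted p = 0.039), Aqp8 35.5-fold and Selenbp1 30.0-fold. Selenbp1 was saturated on 2 of 3 treated and 3 of 4 untreated inflamed arrays, which understates its fold. In untreated mice Hao2 had a log2 difference of -2.88 ± 1.24, Aqp8 -1.53 ± 0.59 and Selenbp1 -2.94 ± 0.86, with adjusted p-values of 0.42, 0.37 and 0.26. The 2 untreated polypoid samples lay far apart for these genes (SD 2.95, 1.38 and 2.02). Within scan session 3 the untreated differences were -4.61, -2.38 and -4.72. Treated minus untreated Selenbp1 in polypoid tissue was -3.64 within session 2 and -0.43 within session 3, with -6.83 and -3 for Hao2 and -4.79 and -2.78 for Aqp8. These examples within an arm were chosen after their values were seen, and in limma no gene passed the test of the difference between the arms (1273 at an unadjusted p under 0.05).

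The untreated arm gave 35 calls (34 higher, 1 lower) and the 5-ASA arm 651 (434 higher, 217 lower), with 2694 and 4072 genes at an unadjusted p under 0.05. Groups did not overlap for 41.8% and 55.1% of genes, against 33.3% by chance. The Wnt list had medians of 2.29 and 2.46 in the 2 arms (adjusted p = 0.10 and 0.14 with an estimated correlation; 2.54 and 3.04 with session as a block), and 3 and 18 members rose, with 20 that rose and 1 that fell in each arm adjusted over the list alone. The colonocyte list had medians of -0.50 and -1.22 (adjusted p = 0.53 and 0.39 with an estimated correlation; -0.65 and -1.56 with session as a block), with 0 and 5 members that fell. Adjusted over the list alone, 2 colonocyte genes fell in the untreated arm, and 18 fell and 1 rose in the 5-ASA arm. Medians in the untreated and 5-ASA arms were 0.02 and -0.99 for interferon response genes and -0.13 and -0.79 for PPAR targets. They were 0.26 and 0.87 for cell cycle and -0.21 and -0.57 for oxidative phosphorylation genes. Among others, smooth muscle (-1.5 and -0.44) and stem cell and fetal-like repair genes (0.92 and 0.57) had the larger median in the untreated arm. Across genes the effects in the 2 arms correlated at r = 0.65, and the highest of the other regroupings of the samples gave 0.42 in size. There were 9 regroupings in all, too few to exclude chance. In both arms inflamed replicate 1 was scanned in session 1 and polypoid replicate 1 in session 2, so a shift between these sessions would enter both effects. In the untreated arm the colonocyte median was -0.27 without untreated polypoid replicate 2, -0.83 without untreated inflamed replicate 2 and -0.90 without untreated polypoid replicate 1. In all, 12 lists passed camera in the untreated and 16 in the 5-ASA arm, 0 in either with an estimated correlation, and 2 and 4 by fry.

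Within scan session 3 all 35 genes called in the untreated arm kept their sign (median size 2.74 against 2.66), and no session held both tissues of the 5-ASA arm. With session as a block limma called 0 genes in either arm (2659 and 2388 at an unadjusted p under 0.05, smallest adjusted p 0.40 and 0.43), and all 35 and all 651 kept their sign. These genes were called from data that held the same samples. The untreated count was 0 without untreated inflamed replicate 1, untreated inflamed replicate 2 or untreated polypoid replicate 2, 7 without untreated polypoid replicate 1, 12 without either treated inflamed sample and 1 without either treated polypoid sample. The 5-ASA count was 0 without treated inflamed replicate 1, 5 without treated inflamed replicate 2, 13 without treated polypoid replicate 1 and 48 without treated polypoid replicate 2.

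**Figure D3:**
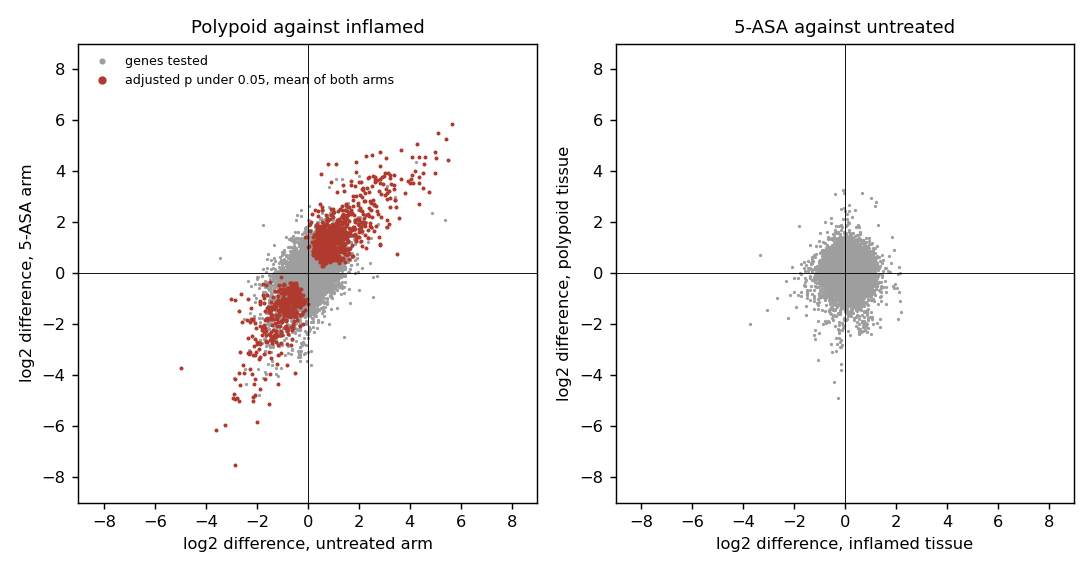
Log2 differences of the genes tested, 1 point per gene. The left panel has polypoid minus inflamed in the untreated arm (horizontal) against the 5-ASA arm (vertical), with red points for genes passing over both arms, and r across genes was 0.65; the right panel has 5-ASA minus untreated in inflamed (horizontal) against polypoid tissue (vertical), where r was 0.04.

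The comparison of 5-ASA with untreated tissue over both tissues (4 samples against 4) addressed the effect of the drug named in the study's title. In limma 0 genes passed, 1361 had an unadjusted p under 0.05, and the smallest adjusted p was 0.76. Without any change, a share of about 0.05 of the 21300 genes would reach that unadjusted p, so such counts are no evidence of an effect by themselves. Il17rd, a regulator of growth factor signalling, had a difference of 0.96 ± 0.12 by 1 of its 4 probes, the retinoblastoma-like gene Rbl2 0.74 ± 0.10, Aspa 1.16 ± 0.18 and the Wnt target Apcdd1 1.90 ± 0.34, all higher with 5-ASA in both tissues. Akr1e1, an aldo-keto reductase, had -1.26 ± 0.16, the carbonyl reductase Cbr3 -1.68 ± 0.29, the mitochondrial fatty acid synthesis gene Mecr -0.77 ± 0.10 and the deacetylase Hdac10 -0.69 ± 0.09. None of these passed. Within scan sessions 1, 2 and 3 Il17rd differed by 0.53, 1.08 and 1.6, Akr1e1 by -0.42, -1.47 and -2.36, and Cbr3 by -0.46, -2.27 and -2.42. Of the 20 genes taken by smallest p, Pank2 (0.61), BC051665 (0.97), Emilin2 (0.76, by 1 of 2 probes), Btf3 (0.49) and H4c9 (0.61) also had positive differences, and Pop5 (-0.64), Mcrip2 (-0.77), Nudt19 (-0.57) and Dad1 (-0.66) had negative differences. Olr1 (-0.95) was not above background in treated inflamed tissue, and its difference is at least 1.70-fold lower by the sample channel.

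Of 30 lists, 11 passed camera over both tissues, 4 higher and 7 lower with 5-ASA, 0 passed with an estimated correlation (smallest adjusted p = 0.67) and 0 by fry (smallest adjusted p = 0.85). With session as a block, the inflamed part of these medians rests on the 1 treated and 1 untreated inflamed sample of scan session 1. The smooth muscle list had a median of -0.70 (-0.99 with session as a block; adjusted p = 0.67 with an estimated correlation), with Cnn1 at -1.30 ± 0.41 and Tagln at -1.11 ± 0.32. The B and plasma cell list had -0.66 (-0.40 with session as a block; adjusted p = 0.67 with an estimated correlation), with Ms4a1 at -2.87 ± 0.99 and Cd79b at -1.88 ± 0.67. Medians of the colonocyte (-0.34), goblet (-0.14), enteroendocrine (-0.17) and NF-kB (0.31) lists and of the cytokine list (0.22) each had an adjusted p of 0.80 with an estimated correlation, and with session as a block they were -0.27, -0.30, -0.34, 0.14 and 0.12. The cytokine and NF-kB lists share Cxcl1 (1.99 ± 0.47) and Ccl20 (2.01 ± 0.61). The Wnt list had 0.28 (0.02 with session as a block; adjusted p = 0.72 with an estimated correlation), oxidative phosphorylation -0.13 and apoptosis 0.13 (both 0.67), and ribosomal proteins -0.10 (0.91), the values in parentheses being adjusted p with an estimated correlation. With session as a block these 3 medians were -0.14, 0.04 and -0.10. Samples whose omission brought a median closer to 0 by more than 1.5 times were as follows. Without untreated polypoid replicate 1, B and plasma cells had -0.11, colonocytes -0.17 and enteroendocrine cells -0.10. Omitting treated polypoid replicate 1 gave 0.03 for cytokines, 0.08 for NF-kB targets and 0.03 for apoptosis, and omitting treated inflamed replicate 2 gave 0.07 for Wnt targets, -0.35 for B and plasma cells, -0.22 for colonocytes, 0.08 for apoptosis and -0.06 for ribosomal proteins. With untreated inflamed replicate 1 left out, B and plasma cells had -0.43, enteroendocrine cells -0.10 and ribosomal proteins -0.04. NF-kB targets had 0.15 and apoptosis 0.06 without untreated inflamed replicate 2. Leaving out untreated polypoid replicate 2 gave 0.11 for cytokines, 0.18 for NF-kB targets and -0.03 for ribosomal proteins, whose median was 0 without treated polypoid replicate 2. Medians moved away from 0 by as much for Wnt targets without treated inflamed replicate 1 (0.50), for cytokines without untreated polypoid replicate 1 (0.35) or treated polypoid replicate 2 (0.47), and for ribosomal proteins without untreated (-0.16) or treated (-0.18) polypoid replicate 1. The same held for enteroendocrine cells (-0.26) and goblet cells (-0.26) without untreated polypoid replicate 2, and for goblet cells (-0.37) without untreated inflamed replicate 2. No member passed over all genes, and adjusted over the list alone 3 Wnt genes rose and 0 genes of the other 10 lists passed.

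The share of genes with no overlap between treated and untreated samples in either tissue and the same direction in both tissues was 6.2%, against 5.6% by chance. A fit of all 15 arrays with the correlation of arrays of an animal estimated called 8 genes (2368 at an unadjusted p under 0.05): Akr1e1, Cbr3, Mecr, Hdac10 and Spink6 lower, and Il17rd, Apcdd1 and an unnamed transcript higher. That fit adds dye-swapped repeats of the same animals, which raises its residual degrees of freedom without adding animals. The list count was 6 without treated inflamed replicate 1 and 7 without untreated inflamed replicate 1.

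In polypoid tissue, 5-ASA was compared with no treatment in 2 samples against 2, which addressed the drug's effect in the lesions. In limma 0 genes passed, 1655 had an unadjusted p under 0.05, and the smallest adjusted p was 0.41. The membrane gene Prom2 had a log2 difference of 1.56 ± 0.15 (1.40 within scan session 2 and 1.73 within session 3), Aspa 1.79 ± 0.26 and Il17rd 1.34 ± 0.17 by 3 of its 4 probes. The protease inhibitor Spink6 had -2.90 ± 0.35 (-3.06 and -2.74), the zymogen granule gene Sycn, saturated on 2 of 4 untreated arrays, -3.57 ± 0.54 (-3.87 and -3.27), Akr1e1 -1.91 ± 0.23 (-1.47 and -2.36) and Mecr -1.27 ± 0.14 (-1.28 and -1.26). Wdr72 (1.03), Srrm4 (1.61), Ube2e2 (1.35), Gxylt2 (1.39) and Adgrg2 (1.46) had positive differences, and Olr1 (-1.62), Pex11a (-0.92), Chchd10 (-1.82) and Dglucy (-1.60) negative ones. None of these passed. Srrm4 and Gxylt2 were well above background on 3 of 4 untreated arrays, and Srrm4 had the sign by 1 of its 2 probes.

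Of 30 lists, 13 passed camera in polypoid tissue, 3 higher and 10 lower with 5-ASA, 0 with an estimated correlation and 0 by fry (smallest adjusted p = 0.14 in both). Oxidative phosphorylation had a median of -0.35, -0.28 within scan session 2 and -0.41 within session 3 (adjusted p = 0.14 with an estimated correlation), and 35 of 40 members had negative differences. The NRF2 and xenobiotic response list had -0.49, -0.16 and -0.38 (adjusted p = 0.14 with an estimated correlation), with Cbr3 at -2.35 ± 0.41. The colonocyte list had -0.54, -0.54 and -0.38 (adjusted p = 0.73 with an estimated correlation), with Aqp8 at -3.78 ± 0.59 and Ceacam20 at -0.95 ± 0.17. B and plasma cells had -0.74, -0.57 and -0.67, and pan-epithelial genes had -0.48, -0.25 and -0.51 (both with an adjusted p of 0.59 with an estimated correlation), with Mzb1 at -1.74 ± 0.50 and Cdx1, an intestinal transcription factor, at -1.07 ± 0.22. The Wnt list had 0.33, 0.38 and 0.34 (adjusted p = 0.73 with an estimated correlation), with Apcdd1 at 2.63 ± 0.48, Wnt10a at 2.49 ± 0.56 and Znrf3 at 1.22 ± 0.20. Cytokines had 0.27, 0.54 and 0.10, with Cxcl1 at 2.94 ± 0.66 and Ccl20 at 2.80 ± 0.87, and cell cycle genes had 0.31, 0.48 and 0.09 (both with an adjusted p of 0.82 with an estimated correlation). Without treated polypoid replicate 1 the cytokine median was -0.01 and the cell cycle median 0.07, while the colonocyte median was -0.84. Without untreated polypoid replicate 1 the colonocyte median was -0.28 and the cytokine median 0.58. Omitting untreated polypoid replicate 2 gave -0.31 for NRF2, 0.12 for cytokines and -0.89 for colonocytes, and omitting treated polypoid replicate 2 gave -0.13 for pan-epithelial genes and 0.75 for cytokines.

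Among the other lists that passed in polypoid tissue, the values within sessions 2 and 3 had opposite signs or a 0 for goblet cells (median -0.26; -0.83 and 0.02), interferon response (-0.32; -0.60 and 0.07), ribosomal proteins (-0.15; 0.16 and -0.48), stem cells and fetal-like repair (-0.24; 0.03 and -0.38) and enteroendocrine cells (-0.19; -0.31 and 0). Their adjusted p-values with an estimated correlation were 0.82, 0.82, 0.82, 0.59 and 0.82, and the ribosomal median was 0.03 under median centring. Adjusted over the list alone, 5 Wnt genes rose, 2 colonocyte genes and 1 NRF2 gene fell, and 0 genes of the other 10 lists passed. Members of these 5 lists included Klk1 (-2.28 ± 0.80), Insl5 (-2.09 ± 0.90) and Krt19 (-1.36 ± 0.41, saturated on 2 of 4 untreated arrays), none of which passed. Without untreated polypoid replicate 1 the interferon median was 0.04, the goblet median -0.14, the enteroendocrine median -0.09, the ribosomal median -0.29 and the stem cell median -0.38. Omitting treated polypoid replicate 2 gave -0.04 for stem cells and fetal-like repair, 0.02 for ribosomal proteins and -0.44 for goblet cells. With untreated polypoid replicate 2 left out, the values were -0.01 for ribosomal proteins, -0.35 for enteroendocrine cells, -0.61 for goblet cells and -0.61 for interferon response, and treated polypoid replicate 1 left out gave -0.10 for goblet cells and -0.32 for ribosomal proteins. With session as a block the list medians in polypoid tissue were unchanged for all 13 lists, because both sessions held 1 sample of each group.

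Treated and untreated polypoid samples did not overlap for 40.5% of genes, against 33.3% by chance. Dye-swapped repeats of the same animals, not further animals, enter the fit of all 15 arrays. The fit of all 15 arrays called 88 genes (59 higher, 29 lower), and the scanner's processed signals gave 1 call, the predicted gene LOC434609 (-3.49, adjusted p = 0.021), while the list count was 8 without untreated polypoid replicate 1.

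In inflamed tissue, 5-ASA was compared with no treatment in 2 samples against 2, which addressed the drug's effect in inflamed mucosa. In limma 0 genes passed, 934 had an unadjusted p under 0.05, fewer than a share of 0.05 of the 21300 genes, and the smallest adjusted p was 0.98. E-cadherin (Cdh1) had a log2 difference of 1.40 ± 0.17 (1.34 within scan session 1), Rbl2 1.20 ± 0.15 (1.25), the purine oxidase Xdh 2.09 ± 0.31 (2.19) and Gpnmb, a glycoprotein of macrophages, 1.69 ± 0.29 (1.37). The phospholipase Pla2g2d had -2.07 ± 0.40 (-2.32), Lims2 -1.34 ± 0.26 (-1.65), Pgls -1.08 ± 0.13 (-1.07) by 1 of its 2 probes and Pop5 -0.89 ± 0.12 (-0.89). Pank2 (0.85), Ermp1 (0.74), BC051665 (1.32), Fhdc1 (1.03), Glrx (0.90) and Axl (0.80) had positive differences, and Psd (-1.18), Lockd (-0.94), Ccdc85b (-0.78), Dad1 (-0.92), Nfil3 (-0.85) and Hps4 (-0.71) negative ones. None of these passed.

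Of 30 lists, 8 passed camera in inflamed tissue, 6 higher and 2 lower with 5-ASA, 0 with an estimated correlation (smallest adjusted p = 0.66) and 0 by fry (smallest adjusted p = 0.82). Smooth muscle genes had a median of -1.03 and -1.67 within scan session 1, with Synm at -3.33 ± 0.78, Cnn1 at -2.30 ± 0.58, Tagln at -2.01 ± 0.45 and Des at -1.84 ± 0.45, Des being well above background on 2 of 3 treated arrays. In untreated inflamed replicate 1 the smooth muscle list stood at 1.54 above the mean of the 8 samples, against 0.43 in replicate 2, and without replicate 1 the median was -0.52. Cell cycle genes had a median of -0.51 and -0.80 within session 1, with 32 of 35 members negative and Mcm6 at -0.72 ± 0.19. Interferon response genes had 0.54 and 0.57, with Ifit1 at 2.10 ± 0.64 and Ifit2 at 2.08 ± 0.45, the latter well above background on 3 of 4 untreated arrays. PPAR targets had 0.38 and 0.44, with the fatty acid transporter Slc27a1 at 2.20 ± 0.68, and pan-epithelial genes had 0.29 and 0.22, with Elf3 at 0.76 ± 0.18. The fibroblast and matrix list had 0.28 and 0.18, with Pdgfra at 1.1 ± 0.34, and the macrophage list had 0.28 and 0.22, with Mrc1 at 1.72 ± 0.60. The cell cycle list stood at -0.91 in treated inflamed replicate 1 and -0.14 in replicate 2 (untreated -0.16 and 0.02), interferon at 0.86 and 0.19 (untreated 0.24 and -0.39) and PPAR targets at 0.95 and 0.03 (untreated 0.29 and -0.44). Without treated inflamed replicate 1 their medians were -0.01, 0.19 and 0. Omitting untreated inflamed replicate 2 gave 0.32 for interferon and 0.16 each for PPAR targets, pan-epithelial and macrophage genes, and omitting treated inflamed replicate 2 gave 0.15 for fibroblast genes, -0.81 for cell cycle genes and 0.60 for PPAR targets. Each of these 7 lists had an adjusted p of 0.66 with an estimated correlation. NF-kB targets had 0.34 and 0.21 (adjusted p = 0.71 with an estimated correlation), with Nfkbiz at 1.44 ± 0.51 and a median of 0.63 without untreated inflamed replicate 1.

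Adjusted over the list alone, 5 smooth muscle genes fell and 1 pan-epithelial gene, Cdh1, rose, and 0 genes of the other 6 lists passed. Treated and untreated inflamed samples did not overlap for 29.4% of genes, against 33.3% by chance. The fit of all 15 arrays, which adds dye-swapped repeats of the same animals, called 2 genes, Xdh and Cdh1, both higher with 5-ASA (1777 at an unadjusted p under 0.05). The list count was 3 without treated inflamed replicate 1, and with session as a block, which for this comparison leaves the 1 treated and 1 untreated sample of scan session 1, 14 lists passed camera.

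The treatment effects in the 2 tissues were compared by their difference, polypoid minus inflamed. In limma 0 genes passed, 1273 had an unadjusted p under 0.05, and the smallest adjusted p was 0.80. The fit of all 15 arrays, which adds dye-swapped repeats of the same animals, called 2 genes, Xdh (-3.92, adjusted p = 0.00057) and Cdh1 (-1.92, adjusted p = 0.038). Across genes the effects in the 2 tissues correlated at r = 0.04, and other regroupings of the samples gave up to 0.45 in size. Of 30 lists, 12 passed camera, 2 with a higher and 10 with a lower effect in polypoid tissue, 0 with an estimated correlation (smallest adjusted p = 0.15) and 0 by fry (smallest adjusted p = 0.13).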

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

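The tests of single samples and of scan sessions for the patterns weighed here were chosen only after the results were seen. For 12 gene lists the treatment effect (5-ASA minus untreated) in polypoid tissue differed from that in inflamed tissue by camera on the difference itself, while with an estimated correlation the smallest adjusted p was 0.15 and by fry 0.13. The values are the median of the difference over the members of a list, then the median effect in inflamed and in polypoid tissue. With session as a block, the inflamed effect rests on treated and untreated inflamed replicate 1 of scan session 1 alone, so the block values are no separate check. The smooth muscle list stood at 1.54 in untreated inflamed replicate 1. Oxidative phosphorylation genes had -0.52 (0.15 and -0.35; camera adjusted p = 6e-08; adjusted p = 0.15 with an estimated correlation; -0.38 with session as a block). NRF2 and xenobiotic response genes had -0.64 (0.24 and -0.49; camera adjusted p = 5.8e-05; adjusted p = 0.15 with an estimated correlation; -0.73 with session as a block). Pan-epithelial genes had -0.81 (0.29 and -0.48; adjusted p = 0.53 with an estimated correlation; block -0.66), and stem cell and fetal-like repair genes had -0.32 (0.04 and -0.24; adjusted p = 0.56 with an estimated correlation; block -0.22). Macrophage and monocyte genes had -0.30 (0.28 and 0.03; adjusted p = 0.70 with an estimated correlation; block -0.17). The other 7 lists had an adjusted p of 0.61 with an estimated correlation. Of these, cell cycle genes had 0.70 (-0.51 and 0.31; block 1.03), smooth muscle genes 1.0 (-1.03 and -0.21; block 1.6), interferon response genes -0.78 (0.54 and -0.32; block -0.70) and mature colonocyte genes -0.63 (-0.02 and -0.54; block -0.72). PPAR target genes had -0.67 (0.38 and -0.08; block -0.62), fibroblast and matrix genes -0.48 (0.28 and -0.24; block -0.27) and B and plasma cell genes -0.80 (-0.12 and -0.74; block -0.42). Of the 12 medians, that of oxidative phosphorylation genes alone came no closer to 0 by more than 1.5 times when any 1 sample was left out. Without treated inflamed replicate 1 the median was 0.33 for cell cycle genes, which stood at -0.91 in that sample and -0.14 in replicate 2 (untreated -0.16 and 0.02), and it was -0.24 for PPAR targets and -0.42 for B and plasma cells. Without untreated polypoid replicate 1 it was -0.40 for interferon, -0.32 for colonocyte, -0.43 for PPAR, -0.01 for fibroblast, -0.03 for macrophage and -0.30 for B and plasma cell genes. Omitting treated polypoid replicate 2 gave -0.39 for NRF2, -0.49 for pan-epithelial, -0.31 for fibroblast, -0.03 for macrophage and 0.55 for smooth muscle genes. Omitting untreated inflamed replicate 2 gave -0.23 for PPAR, -0.18 for macrophage and -0.12 for B and plasma cell genes. Smooth muscle genes had 0.45 without untreated inflamed replicate 1 and 0.51 without untreated polypoid replicate 2, B and plasma cell genes -0.35 without the latter, and stem cell genes -0.19 without treated inflamed replicate 2. Medians moved away from 0 by as much for macrophage (-0.49) and stem cell genes (-0.54) without untreated inflamed replicate 1, for fibroblast (-0.79), interferon (-1.24) and macrophage genes (-0.59) without untreated polypoid replicate 2, and for cell cycle genes (1.17) without treated inflamed replicate 2.

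In polypoid tissue the colonocyte, enteroendocrine, goblet and B and plasma cell lists had lower medians with 5-ASA, with a mean of -0.43 over the 4 lists (adjusted p = 0.73, 0.82, 0.82 and 0.59 with an estimated correlation). No table excluded that untreated polypoid replicate 1 held more adjacent mucosa: without it the mean was -0.26, or 59.5% of its size, and the medians were -0.28, -0.09, -0.14 and -0.53 against -0.54, -0.19, -0.26 and -0.74, while in that sample the colonocyte and enteroendocrine lists stood at 0.26 and 0.27, against -0.74 and -0.80 in untreated polypoid replicate 2. The mean was -0.56 within scan session 2, which held that sample, and -0.26 within session 3, and a shift shared by the samples of a session cancels in both, since each session held 1 treated and 1 untreated sample. Within sessions 2 and 3 the goblet medians were -0.83 and 0.02, the enteroendocrine -0.31 and 0, the colonocyte -0.54 and -0.38 and the B and plasma cell -0.57 and -0.67, and the difference between the sessions cannot be told apart from that between their single samples. The goblet list stood at 0.22 and -0.45 in untreated polypoid replicates 1 and 2 and at -0.77 and -0.27 in the treated ones. For the B and plasma cell list the values were 0.15 and -0.02 against -0.74 and -0.86, so both untreated samples lay above both treated ones. An effect of 5-ASA on the cells of the 4 lists stays open as a hypothesis, as does more adjacent mucosa in 1 sample, because 2 samples per group leave no further sample to decide between them.

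In inflamed tissue the smooth muscle list had a median of -1.03 with 5-ASA (adjusted p = 0.66 with an estimated correlation). Without untreated inflamed replicate 1 it was -0.52, or 50.8% of its size, and the list stood at 1.54 in that sample against 0.43 in untreated inflamed replicate 2 and -0.31 and 0.07 in the treated samples. More muscle in the area captured from that sample may account for part of the difference, and no table excluded it. A lower share of muscle with 5-ASA stays open as untested.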

How the results depend on the processing

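Leaving out untreated inflamed replicate 1 and untreated polypoid replicate 1 together, scan session as a random block, and session as a fixed block for the gene lists were chosen only after the results were seen. Of 25 other settings, the count for polypoid over inflamed tissue stayed within 1.5 times 1265 except with all 15 arrays and the correlation within an animal estimated (3360), with session as a fixed block (0, with 1 residual degree of freedom) and when single samples were left out (125 without treated inflamed replicate 1 to 1325 without untreated polypoid replicate 1). The count of 35 in the untreated arm was 118 with the scanner's processed signals, 11 without a filter on dim probes, 1022 with all 15 arrays, 17 with a replicate block, 0 with session as a fixed block, 0 with sample weights, 22 with the series matrix values, 53 with session as a random block, 0 with both samples left out and 0 to 12 with 1 sample left out. With the processed signals the median of all genes was -0.115 in that arm and 0.111 for the difference of the treatment effects. The count of 651 in the 5-ASA arm was 1088 with the processed signals, 2644 with all 15 arrays, 1088 with a replicate block, 0 with session as a fixed block, 1669 with sample weights, 419 with the series matrix values, 1177 with both samples left out and 0 to 893 with 1 sample left out. For 5-ASA over untreated, limma gave 0 calls in every setting except all 15 arrays (8 over both tissues, 88 in polypoid tissue, 2 in inflamed tissue and 2 for the difference) and the processed signals (1 in polypoid tissue), with 934 to 1655 genes at an unadjusted p under 0.05 in the values reported first. Replicate numbers were not used as pairs: across genes, which are not independent replicates, residuals of equal numbers correlated at 0.03 to 0.36, and each replicate 1 was scanned in session 1 or 2 and each replicate 2 in session 3 or 4, so the number goes with session. Of the gene lists past camera, 0 passed in any comparison with an estimated correlation, and by fry 5 passed for polypoid over inflamed tissue, 2 in the untreated arm, 4 in the 5-ASA arm and 0 for the treatment and the difference. With session as a fixed block 8 lists passed for polypoid over inflamed tissue and 14 for 5-ASA in inflamed tissue (1 sample against 1), and with both samples left out 4 passed for 5-ASA over both tissues and 8 in polypoid tissue. With 1 sample left out 15 to 18 lists passed for polypoid over inflamed tissue, 6 to 12 for 5-ASA over both tissues, 8 to 14 in polypoid tissue, 3 to 11 in inflamed tissue, 8 to 14 in the untreated arm, 15 to 19 in the 5-ASA arm and 8 to 15 for the difference. Where this left a group with 1 sample, that sample was assumed to vary like the other groups. Of 440 list medians under 5 other scalings, 1 had the other sign, ribosomal proteins with 5-ASA in polypoid tissue (0.03 with median centring). Of 7795 values of named genes under other settings, 6960 kept their direction and side of the threshold, 749 no longer passed, 83 came to pass and 3 turned sign: Cdh17 with 5-ASA in inflamed tissue with the processed signals (-0.14), Srrm4 with 5-ASA in polypoid tissue with a filter on all arrays (-0.76) and Nos1 for polypoid over inflamed tissue with session as a fixed block (0.32). Of the 2727 values of named genes that passed, 1978 still passed in the same direction and 0 turned. The fit of all 15 arrays adds dye-swapped repeats of the same animals, which raises its residual degrees of freedom without adding animals. Apart from this, the fewer degrees of freedom with the fixed block and the fewer samples when some were left out, the cause was not tested. Signal over background limited genes that were dim in inflamed tissue, such as Lcn2 and Retnlg, well above background on 3 and 2 of 7 arrays, and it was lowest in treated inflamed replicate 2 (57.4% of spots).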

Other observations

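The tests of the Wnt pattern were chosen only after the result was seen, and the counts of other splits were planned. The genes named in this part were chosen after their values were seen, and log2 differences are polypoid over inflamed tissue over both arms unless another comparison is named.

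In polypoid against inflamed tissue, 14 fixed lists did not pass camera, although single members did in all but the macrophage, red blood cell and ribosomal protein lists. In the prostaglandin and leukotriene list the lipoxygenase Alox12 (3.02 ± 0.14) and the exporter Abcc4 (2.46 ± 0.22) rose, and the prostaglandin transporter Slco2a1 (-1.86 ± 0.14) and the receptor Ptger3 (-0.90 ± 0.18) fell, with a median of 0.13 (camera adjusted p = 0.52; 0.14 within scan session 3; 0.19 with session as a block). Ptgs2, the inducible cyclooxygenase, had 2.14 ± 0.98 (adjusted p = 0.26), and the prostaglandin-degrading Hpgd had -2.42 ± 0.75 (adjusted p = 0.12). With 5-ASA over both tissues this list had a median of -0.04 and a mean of 0.03 (camera adjusted p = 0.73). In the NRF2 and xenobiotic list Abcc2 (1.92 ± 0.18; well above background on 5 of 7 inflamed arrays), Gsta4 (1.59 ± 0.24) and Hmox1 (0.83 ± 0.12) rose, and Cyp2s1 (-2.74 ± 0.29), Cyp3a13 (-2.65 ± 0.38) and Gstm1 (-1.45 ± 0.21) were among 7 that fell, with a median of -0.17 (camera adjusted p = 0.15; session 3 -0.36; block -0.31).

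Among Paneth cell and antimicrobial genes Defa20 (4.07 ± 0.55; 6 of 7 inflamed arrays), Reg3g (3.25 ± 0.65; 1.16 within scan session 3; saturated on 4 of 8 polypoid arrays), Mmp7 and Lcn2 rose and Mptx1 fell (median 0.35; camera adjusted p = 0.25; session 3 0.41; block 0.35). The histidine decarboxylase Hdc (1.96 ± 0.16; 6 of 7 inflamed arrays) and the protease Mcpt1 (0.95 ± 0.16) rose among mast cell genes (median 0.42; camera adjusted p = 0.17; session 3 0.20; block 0.31). Among immediate early and heat shock genes Ier3 (3.05 ± 0.33), Myc (1.89 ± 0.29, by 2 of 3 probes), Nr4a1 (0.95 ± 0.18) and Jun (0.78 ± 0.13) rose (median 0.22; camera adjusted p = 0.18; session 3 0.11; block 0.32). Klf4 fell (-1.68 ± 0.19, or 3.19-fold, relative to the reference and 4.44-fold by the sample channel), but it was saturated in treated inflamed tissue, so neither fold is exact. Ier3 and Cxcl1 were the 2 NF-kB targets that rose (median 0.19; camera adjusted p = 0.45; session 3 0.30; block 0.23). Among apoptosis genes Bmf (1.66 ± 0.13, by 1 of 2 probes) rose and Tradd (-1.03 ± 0.12) fell (median 0.16; camera adjusted p = 0.51; session 3 0.24; block 0.15).

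Among pan-epithelial genes Cldn4 rose and Cdx1 (-1.14 ± 0.15) and Phgr1 (-1.75 ± 0.35) fell (median -0.23; camera adjusted p = 0.17; session 3 0.04; block -0.04). Among fibroblast and matrix genes Mmp10 (3.14 ± 0.60), Vim (1.06 ± 0.20) and Timp1 (0.96 ± 0.18) rose and Postn (-2.16 ± 0.42) fell (median 0.05; camera adjusted p = 0.58; session 3 0.12; block 0.01). Prox1 (3.39 ± 0.28, by 2 of 3 probes; 6 of 7 inflamed arrays), also a Wnt target in the fixed lists, was the endothelial gene that rose, and that list had a median of -0.09 and a mean of 0.11 with a test toward lower values (camera adjusted p = 0.58; session 3 -0.11; block -0.09). Gsdma (1.39 ± 0.23) and Sfn (0.85 ± 0.17) rose among squamous epithelium genes, whose median was -0.03 and mean 0.15 with a test toward higher values (camera adjusted p = 0.62; session 3 -0.02; block -0.04). In limma no macrophage, red blood cell or ribosomal protein gene passed, and the haemoglobin gene Hba-a1 (-0.89 ± 0.20, adjusted p = 0.055) was the only one to pass adjusted over its list alone. Their medians were -0.06, -0.05 and 0.03 (camera adjusted p = 0.52, 0.58 and 0.60; session 3 0.03, -0.15 and 0.10; block 0, -0.16 and 0.11). Adjusted over the list alone, the genes that rose and fell were 3 and 2 in the prostaglandin list, 5 and 8 in NRF2, 4 and 2 in Paneth, 3 and 0 in mast cell, 5 and 1 in immediate early, 3 and 2 in NF-kB, 2 and 1 in apoptosis, 1 and 4 in pan-epithelial, 3 and 1 in fibroblast, 1 and 0 in endothelial and 2 and 0 in squamous genes.

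The Wnt and beta-catenin target list had a median of 2.26 in polypoid over inflamed tissue (camera adjusted p = 3.8e-19; adjusted p = 0.13 with an estimated correlation). Scan session was argued against as the whole cause, because within session 3 the median was 2.80. A lower share of differentiated epithelium that raised the genes of every other cell type alike was argued against. The highest median among 8 lists of other cell types, that of mast cells, was 0.42, or 18.8% of the Wnt median. These 8 lists held no epithelial cell type, so a shift within the epithelium was not tested. The neutrophil list (1.03) was not among those 8. Higher Wnt signalling in the epithelium of the polyps is a hypothesis, and a different share of Wnt-active cells stays open as untested.

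For polypoid against inflamed tissue in a model with the 2 groups alone, chance was argued against but not excluded. The real split of the 8 samples called 1293 genes, the most of any of the 35 splits, and the highest other called 46. A share of 1 in 35 is the smallest that this count can reach. The splits took the samples as exchangeable, although scan session 1 held only inflamed and session 2 only polypoid samples. The count therefore does not separate tissue from session. For 5-ASA against untreated chance is not excluded: the real split called 0 genes, which every one of the 35 splits reaches by definition, so this count tests nothing, and the highest other, which was the split by tissue, called 1293. That split points to a structure of the samples, their tissue, with which scan session partly goes. In limma the treatment comparison of 4 groups had 1361 genes at an unadjusted p under 0.05.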
